A study of Rattus norvegicus with 30 samples.

How the data were processed

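RNA from the livers of 30 Wistar rats was measured on Affymetrix Rat Gene 2.0 ST arrays, 1 array per rat. The rats fell into 5 groups of 6, taken from the treatment stated for each rat: partial hepatectomy of 30, 70 or 90% of the liver (PH30, PH70, PH90), a sham operation, or no operation. Tissue was taken 24 hours after surgery and frozen, and RNA was labelled with biotin and hybridised, per the labels' protocols. Each rat has a number of its own, which is used as its name and pairs no rats across groups. The numbers of the unoperated rats (145 to 152) are higher than those of all other rats (37 to 143), so a drift with the order of the rats cannot be told apart from the lack of an operation.

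The authors deposited 1 table of processed values, with 29489 probe sets and 30 columns, 1 per rat, and no missing values. Per the submitters' processing notes the values were made with the robust multi-array average (RMA) in Affymetrix Expression Console, and the versions are not given in the sources used here. RMA corrects the background, equalises the distribution of the arrays and summarises the probes of a probe set on a log2 scale. The deposited log2 values run from -6.04 to 5.44, and the median of every probe set over the 30 arrays is 0 within 5e-07, so each probe set was centred on its median before deposit. The table itself states neither scale nor centring, and log2 is taken from RMA. Differences between arrays are kept by such centring. Levels are lost, so no gene is called abundant, faint or absent here, and no gene's level is set against another's. Column medians lie between -0.009 and 0.022, so the arrays were on a common scale. Signal over background is not known for these values, and the precision of a result is limited by the number of arrays, 6 per group.

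Probe sets were named from the platform's annotation. Of the 29489 probe sets, 18511 had exactly 1 gene symbol, 575 had several and 10403 were listed with no gene. The Entrez ID of 18394 of the 18511 was present in a RefSeq gene table of the rat (assembly GRCr8), which changed 0 symbols. The 18511 probe sets represent 18166 genes. Because levels are lost, the low-value filter and the brightest probe set planned before the data were examined could not be applied. Every gene was tested, and the 291 genes with more than 1 probe set were represented by the mean of their probe sets, which correlate below 0 for 74 of them. Probe sets with several symbols or none are not used in the comparisons between groups.

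Genes were tested with limma 3.58.1 in R 4.3.3: lmFit on all 30 arrays with 1 mean per group, eBayes with its default prior, two-sided, and Benjamini-Hochberg adjustment over the 18166 genes of each comparison. A gene is called at an adjusted p below 0.05. The spread is shared by the 5 groups, with 25 residual and 3.71 prior degrees of freedom. The comparisons were sham against unoperated, each resection against sham, and the 3 pairs of resections, plus limma's moderated F test for any difference between PH30, PH70 and PH90. A log2 fold change is the mean of the group named first minus that of the other, and SE is its moderated standard error. A count of rats beside a change is of rats in the group named first on that side of the other group's mean. The groups can still overlap. Every adjusted p in the text is limma's unless a permutation test is named.

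Before the data were examined, 34 gene lists were fixed: cell cycle, stress, acute phase, hormone, metabolic, secretory and zonation genes of the liver and markers of 9 other cell types. Each list was tested with limma's camera (correlation between genes preset at 0.01), two-sided and adjusted over the 34 lists of a comparison, and again with the correlation estimated from the data, which allows for members that vary together. With the preset correlation many lists were also called when rats were regrouped at random, so its adjusted p values are descriptive. The fry test was run as an alternative. It asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. Members that rose, fell or did not pass are counted from the gene fits, adjusted over all genes tested and also over the list alone. The mean of a list's genes on each array describes single rats. The genes open to naming were fixed at the same time: in each comparison the 8 called genes with the largest rise and the 8 with the largest fall, up to 4 called members of each list by size of change (or 2 members where none was called), and 10 genes followed in every comparison whatever the result (Mki67, Ccnd1, Cdk1, Cdkn1a, Myc, Afp, Alb, Cyp7a1, Igf1 and Hgf). The selection holds 802 pairs of a gene and a comparison. The text names part of it, chosen after the values were seen, with preference for genes whose call did not depend on a single array, so the share of stable calls among named genes is higher than in the whole selection.

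The steps were tested on simulated data before use. In simulated values for PH90 against sham over 18166 genes, with 50 changed genes of each size, true log2 changes of 0.25, 0.5, 1 and 2 were recovered in 36, 84, 96 and 100% of cases, with 9 false calls among unchanged genes. The simulated genes varied independently of each other and with the same spread in every group. The real arrays differ in both, so these rates do not describe the real data. Overlaps between comparisons that share the sham arrays are set beside 100 simulations of unchanged groups and beside values from separate parts of the sham group. Each simulation took the residuals of arrays drawn from all groups, with random signs, and used 1 set of them as the common control.

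Other settings tried were all probe sets as units, array weights, a robust prior, a fit of only the groups compared, the animal number as a covariate, centring of arrays, unoperated rats as control, a 2-fold threshold and leaving out each array in turn. After the data were seen, 3 more were added: the fit without PH30 rat 95 and PH70 rat 139, the probe set with the largest SD for each gene, and the upper part of the genes by SD. In a comparison that includes neither PH30 nor PH70, leaving out these rats keeps every fold change and alters only the shared spread. A filter at the 50th percentile of level, quantile normalization and a prior that follows the level were planned and not run, since they need levels. Other ways of assigning rats to groups were drawn 100 times per comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.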

Results

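Gene expression was measured in the livers of 30 Wistar rats, 24 of them taken 24 hours after surgery. Partial hepatectomy, the removal of part of the liver, is the classic model of liver regeneration, in which the remnant grows back. The rats had lost 30, 70 or 90% of the liver (PH30, PH70 and PH90), had a sham operation, or had no operation, with 6 rats in each of the 5 groups. The title of the series asks how expression in the remnant varies with the size of the resection. Values are differences on the log2 scale between arrays that carry 18166 named genes. Levels of single genes are not known, because the deposited values were centred on the median of each probe set.

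The PH90 livers stood apart from all others. On the first principal component, which carried 45.7% of the variance, the 6 PH90 arrays lay between 34.75 and 59.45 and the other 24 arrays at 10.63 or below. The second component (15.1%) parted 5 of the 6 PH70 arrays, between -30.14 and -20.08, from the sham arrays, between 9.91 and 12.56. One array of PH30 and one of PH70 lay away from their groups. PH30 rat 95 had a mean correlation of -0.113 with the other PH30 arrays, which correlated at 0.18 to 0.245, and of 0.498 with PH70. PH70 rat 139 had a mean correlation of -0.114 with the other PH70 arrays, which correlated at 0.493 to 0.546, and of 0.203 with sham. Both rats stayed in all comparisons. The number of genes called in a comparison is given again without them where it moves by more than 1.5 times, and the members called are given again for some of the lists.

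**Figure D1:**
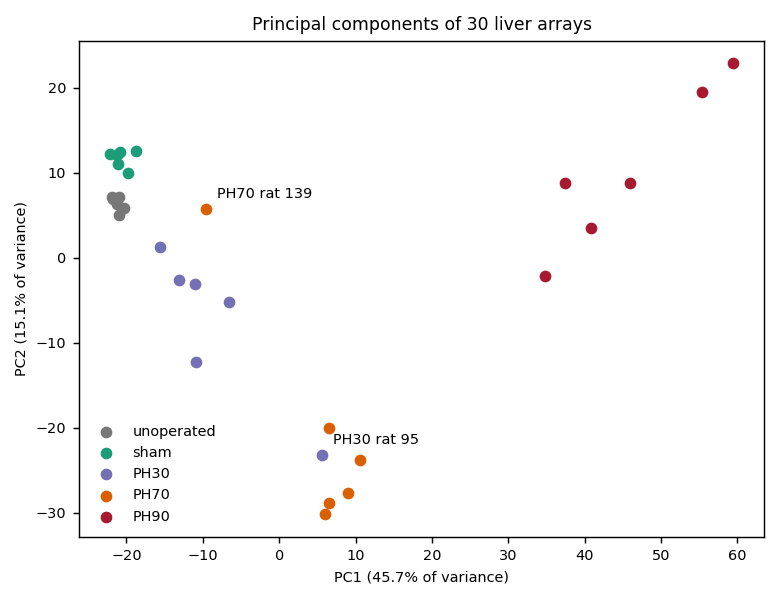
Arrays on the first and second principal components (45.7 and 15.1% of the variance), 1 point per rat, coloured by group. The 6 PH90 arrays lie at 34.75 or above on the first component, and PH30 rat 95 and PH70 rat 139 lie away from the other arrays of their groups.

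Acute phase proteins, plasma proteins that the liver makes after injury, were higher in sham-operated than in unoperated rats. Lcn2, an iron-scavenging protein of the innate defence, was 13.2-fold higher in sham than in unoperated rats (log2 difference 3.72, SE 0.46, adjusted p = 1.4e-05), in 6 of 6 rats. A2m, a broad protease inhibitor, was 9.75-fold higher (3.28, SE 0.37, adjusted p = 2.4e-06). Lbp, which binds bacterial lipopolysaccharide, and Orm1 were 3.67-fold and 3.17-fold higher. Of 24 measured acute phase genes 11 rose and 0 fell, with 18 rising adjusted over the list alone. The list test gave an adjusted p of 9.9e-35, and adjusted p = 4.2e-05 with an estimated correlation.

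C4bpa, C9, C5 and C8a, 4 genes of the complement system on the list of 34 secreted plasma proteins, rose by 1.77-fold, 1.62-fold, 1.6-fold and 1.46-fold. Complement genes were not tested as a list. The 4 were the 4 members of that list that rose, 1 fell, and the median of the list was 0.02 (adjusted p = 0.013, and adjusted p = 0.52 with an estimated correlation). Kng1, the precursor of kinins (1.68, SE 0.1, adjusted p = 1.3e-12), Prg4 (1.54) and Gas6, a ligand of the TAM receptors (1.3), were among the genes with the largest rises. Steap3, a metalloreductase of iron uptake, fell 2.6-fold (-1.38, SE 0.13, adjusted p = 9.3e-08). Tymp, a thymidine phosphorylase, fell 2.3-fold and Cxcl13, which attracts B cells, 2.19-fold. Among 15 red cell markers Hbb-b1, a beta globin, rose by 1.13 and Car1, an erythroid carbonic anhydrase, fell by 0.79, around a list median of 0.06 (adjusted p = 0.21).

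Mitosis genes tended the other way. Their list median was -0.63 in sham against unoperated rats, with 0 of 37 members called (list test adjusted p = 2.6e-11, adjusted p = 0.52 with an estimated correlation). The mean of the list was -0.58 ± 0.06 (SD, n = 6) in sham and 0.08 ± 0.08 in unoperated rats, a difference of -0.66 with a two-sided exact permutation p of 0.0022, the smallest that 6 against 6 rats can give. Mki67, the proliferation antigen, differed by -1.57 (SE 0.52, adjusted p = 0.18) and Top2a by -1.42 (adjusted p = 0.23), both lower in 6 of 6 rats. At an unadjusted p below 0.05 limma had 13 lower and 0 higher, and in a fit of these 2 groups alone, which leaves out the resected groups, 31 of the 37 were called lower. Conjugation enzymes (median -0.32, 1 of 23 fell, adjusted p = 7.6e-06) and lipogenesis (median -0.15, 0 of 20 passed, adjusted p = 0.002) were lower as lists, with adjusted p = 0.22 and adjusted p = 0.39 with an estimated correlation. Macrophage markers (median 0.21, 0 of 20 passed, adjusted p = 1.4e-05) and the unfolded protein response (median 0.17, 0 of 23 passed, 8 rose and 1 fell adjusted over the list alone, adjusted p = 6.4e-05) were higher as lists, each with adjusted p = 0.52 with an estimated correlation. Cholesterol synthesis was also higher as a list (median 0.27, 0 of 19 passed, adjusted p = 8.1e-05, adjusted p = 0.52 with an estimated correlation), and neutrophil and T and NK cell markers (medians 0.09 and 0.07, 0 of 16 and 0 of 21 passed) had list adjusted p of 0.016 and 0.013, with adjusted p = 0.52 and adjusted p = 0.39 with an estimated correlation. Fatty acid oxidation was lower (median -0.08, 1 of 27 fell, adjusted p = 0.041, adjusted p = 0.61 with an estimated correlation). In the fit of the 2 groups alone 6 conjugation, 7 lipogenesis and 4 fatty acid oxidation genes fell, and 8 genes of the unfolded protein response, 2 macrophage markers and 1 cholesterol gene rose. Without rats 95 and 139, 5 conjugation enzymes fell and 3 genes of the unfolded protein response rose, with 1 falling in both fits. Those rats are in neither group, so leaving them out changed only the shared spread and no fold change here.

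In all 134 genes were called, 56 higher and 78 lower in sham. The count was 721 in a fit of these 2 groups alone, with 31.6% of them higher in place of 41.8%, 539 with array weights, 316 without rats 95 and 139, and 87, 79 and 70 without sham rat 45, sham rat 112 or unoperated rat 152. The unoperated rats carried the highest animal numbers, so order and operation cannot be told apart.

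**Figure D2:**
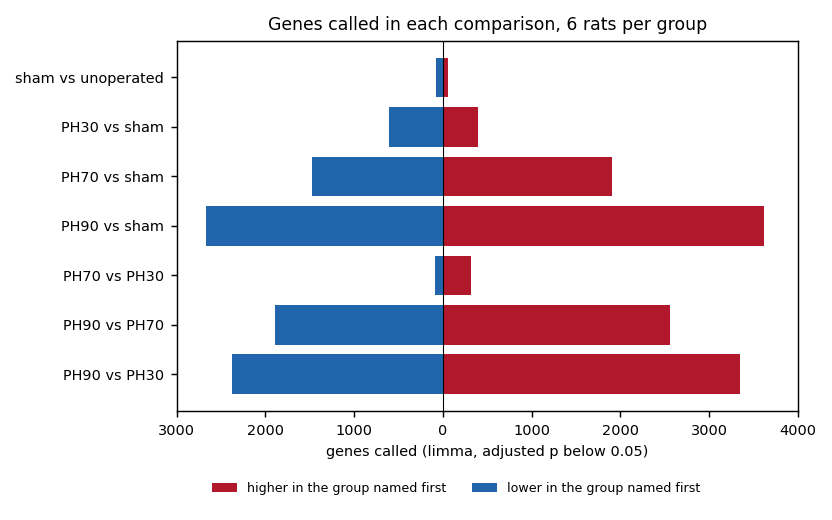
Number of genes called (limma, adjusted p below 0.05) in 7 comparisons of 6 against 6 rats; bars to the right count genes higher in the group named first and bars to the left genes lower in it. The counts rise from 1005 in PH30 to 3386 in PH70 and 6290 in PH90 against sham.

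Against this sham background, removal of 30% of the liver raised genes of DNA replication and cell division. Rrm2, a subunit of the ribonucleotide reductase that makes DNA precursors, rose 6.44-fold (2.69, SE 0.6, adjusted p = 0.0088), Mki67 5.01-fold (2.33, SE 0.52, adjusted p = 0.0092) and Ccna2, the cyclin of S phase, 3.41-fold (1.77, SE 0.45, adjusted p = 0.018), each in 6 of 6 rats. Mcm6, part of the replicative helicase, rose 2.72-fold, and H2ax, a histone of DNA damage signalling, 3.24-fold. Of 37 DNA replication genes 11 rose and 0 fell (31 rose adjusted over the list alone), with a list adjusted p of 5.4e-17 and adjusted p = 0.44 with an estimated correlation. Of 37 mitosis genes 6 rose and 0 fell (35 adjusted over the list alone), with a list adjusted p of 5.9e-18 and adjusted p = 0.48 with an estimated correlation.

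These rises were unequal between rats. The mean of the mitosis genes was 2.29 in PH30 rat 95 and between -0.27 and 0.93 in the other 5 PH30 rats, against -0.63 to -0.47 in sham. Without rats 95 and 139 the list medians were lower, 0.37 in place of 0.53 for DNA replication and 0.67 in place of 1.04 for mitosis, while 19 and 25 members were called. The control mattered as well, since mitosis genes were lower in sham than in unoperated rats. Against unoperated rats 8 of 37 DNA replication genes and 0 of 37 mitosis genes were higher in PH30, and the mitosis mean differed by 0.4 (two-sided exact permutation p = 0.43). Rrm2 then differed by 1.14 (adjusted p = 0.24), Mki67 by 0.76 (adjusted p = 0.4) and Ccna2 by 0.46 (adjusted p = 0.58).

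Genes of hepatocyte metabolism and secretion fell in PH30. Cyp2c11, the main male-specific P450 of the rat, fell 1.75-fold (-0.81, SE 0.18, adjusted p = 0.0081), Otc, an enzyme of the urea cycle, 1.5-fold (-0.59, SE 0.13), and Slc25a15, the ornithine carrier of the mitochondria, 1.79-fold. Bdh1, an enzyme of ketone body formation, fell 1.91-fold. Pros1, the anticoagulant protein S, fell 1.79-fold (-0.84, SE 0.15, adjusted p = 0.0032) and F9, a clotting factor, 1.31-fold (-0.39, SE 0.09), although F9 differed by -0.1 (adjusted p = 0.52) from unoperated rats. By list, 6 of 29 P450 genes fell (8 adjusted over the list alone), as did 5 of 23 conjugation enzymes, 3 of 32 urea cycle and amino acid genes (8 adjusted over the list alone), 7 of 34 secreted plasma proteins and 3 of 27 fatty acid oxidation genes, and 0 members of these lists rose. Leaving out rats 95 and 139, 7 urea cycle and amino acid genes and 6 fatty acid oxidation genes fell. Their list tests gave adjusted p of 7.3e-05, 0.00014, 6.3e-09, 3.9e-07 and 0.00018. With an estimated correlation the first 4 had adjusted p = 0.27 and the last adjusted p = 0.48. Gluconeogenesis and glycogen genes fell in 3 of 16 (adjusted p = 0.036, adjusted p = 0.67 with an estimated correlation) and periportal genes in 1 of 17 (adjusted p = 0.025, adjusted p = 0.48 with an estimated correlation). On the immediate early and G1 list 1 of 20 rose and 1 fell (adjusted p = 0.035, adjusted p = 0.48 with an estimated correlation). These 3 lists lost their calls without rats 95 and 139 (adjusted p = 0.22, 0.064 and 0.071), with medians of -0.11, -0.23 and 0.18 in place of -0.13, -0.23 and 0.18 and with 1 of 16 and 2 of 17 lower and 2 of 20 higher, as the last did against unoperated rats (adjusted p = 0.36).

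Other large falls were in single genes. Stac3, known from the calcium release of muscle, fell 2.69-fold (-1.43, SE 0.31, adjusted p = 0.008), Nox4, an NADPH oxidase, 2.36-fold, Rdh16, a retinol dehydrogenase, 2.3-fold, Inmt 2.17-fold and Fmo1, a flavin monooxygenase, 2.12-fold. Of 24 acute phase genes 3 rose (list adjusted p = 0.036, adjusted p = 0.67 with an estimated correlation, adjusted p = 0.083 in a fit of the 2 groups alone). Among them was Timp1, an inhibitor of matrix metalloproteinases (1.18, SE 0.3, adjusted p = 0.019), higher in 5 of 6 rats. It lost its call without PH30 rat 98 or sham rat 41, 45 or 114, where the change in 12 such fits ranged from 1.04 to 1.53, and in a fit of the 2 groups alone (adjusted p = 0.085). Of the marker lists of other cells 0 of 9 were called. Single markers changed within these lists: Marco, a macrophage scavenger receptor, rose by 0.84 (list median 0.04) and Krt18, a keratin shared by hepatocytes and bile duct cells, by 0.77 (list median 0.04). Hbb-b1 was lower than in sham (-0.68, SE 0.17, adjusted p = 0.018), a call lost without PH30 rat 130 or sham rat 143, where the change in 12 such fits ranged from -0.76 to -0.57, and it was 0.46 above unoperated rats (adjusted p = 0.089). The unfolded protein response, with 1 of 23 higher and 2 lower than sham (adjusted p = 0.69), was higher than in unoperated rats as a list (adjusted p = 0.026). Macrophage and neutrophil markers were also higher than in unoperated rats (adjusted p = 0.00082 and 0.0011), with 4 of 20 and 2 of 16 called.

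In all 1005 genes were called, 399 higher and 606 lower. The count was 1984 without rats 95 and 139, 1938 with array weights and 1789 against unoperated rats, and 1527, 626 and 629 without PH30 rat 95, PH30 rat 65 or sham rat 143.

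After removal of 70% of the liver nearly all replication and mitosis genes rose. Rrm2 rose 25.5-fold (4.67, SE 0.6, adjusted p = 4.9e-06), Mki67 12.7-fold (3.67, SE 0.52, adjusted p = 1.3e-05), Top2a, the topoisomerase of dividing cells, 12-fold (3.59, SE 0.52) and Plk1, a kinase of mitosis, 7.16-fold, each above the sham mean in 6 of 6 rats. Mcm6 rose 5.91-fold and Pcna, the sliding clamp of DNA polymerases, 4.35-fold. All 37 mitosis genes rose, with a median of 2.16, and 35 of 37 DNA replication genes, with a median of 1.14. The list tests gave adjusted p of 1.3e-35 and 6.8e-34, and adjusted p = 0.2 for both with an estimated correlation. PH70 rat 139 did not share the rise: its mitosis mean was -0.19 and its DNA replication mean -0.06, against 1.21 to 2.29 and 0.95 to 1.34 in the other 5 rats. Against unoperated rats 36 mitosis and 35 DNA replication genes were called higher.

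Genes of cell growth rose to a smaller degree. Ccnd1, cyclin D1 of the G1 phase, rose 2.82-fold (1.49, SE 0.29, adjusted p = 0.00035) in 5 of 6 rats, and Cdkn1a, which encodes the cell cycle inhibitor p21, 2.35-fold. Of 27 ribosome biogenesis genes 14 rose and 0 fell (17 adjusted over the list alone), for example Nop58 by 0.9 and Ncl, nucleolin, by 0.58 (list adjusted p = 1.1e-07, adjusted p = 0.27 with an estimated correlation). Of 17 p53 targets 6 rose, with Ccng1 up by 0.89 (adjusted p = 0.0074, adjusted p = 0.26 with an estimated correlation). The immediate early list had 3 rising and 1 falling member of 20 (adjusted p = 0.015, adjusted p = 0.29 with an estimated correlation), the one that fell being Dusp1, a phosphatase of MAP kinases (-1.57, SE 0.28). In the oxidative stress list 6 of 20 rose and 1 fell (adjusted p = 0.015, adjusted p = 0.26 with an estimated correlation). Against unoperated rats the p53, immediate early and oxidative stress lists lost their calls (adjusted p = 0.11 for each), with 3 of 17 p53 targets higher and 1 lower.

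Falls again covered hepatocyte functions. P450 genes fell in 11 and rose in 2 of 29 (median -0.42, adjusted p = 8e-05), with Cyp2b1, a drug-inducible P450, 2.68-fold and Cyp2c11 2.14-fold lower. Secreted plasma proteins fell in 15 of 34 (19 adjusted over the list alone, adjusted p = 1.8e-09), with Pros1 down by 1.07 (SE 0.15) and F11, a clotting factor, by 0.95. Urea cycle and amino acid genes fell in 11 of 32 (adjusted p = 1.3e-05), among them Otc, 1.91-fold. With an estimated correlation these lists had adjusted p = 0.2, adjusted p = 0.2 and adjusted p = 0.26. Cholesterol synthesis fell in 5 of 19 (adjusted p = 0.00057, adjusted p = 0.4 with an estimated correlation). In the fit without rats 95 and 139 this was 11 of 19, but against unoperated rats the median was -0.07 in place of -0.37, 1 of 19 fell and the call was lost (adjusted p = 0.28). Bile acid genes fell in 4 of 24 (8 without the 2 rats), among them Slc10a1, the main bile acid importer, 1.78-fold (adjusted p = 0.025, adjusted p = 0.41 with an estimated correlation). Periportal hepatocyte genes fell in 4 of 17 (adjusted p = 0.015, adjusted p = 0.29 with an estimated correlation) and pericentral genes in 5 of 15 (adjusted p = 0.093, and 0.025 against unoperated rats).

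Conjugation enzymes fell in 7 of 23 (adjusted p = 0.0022), gluconeogenesis and glycogen genes in 5 of 16 (adjusted p = 0.015), and fatty acid oxidation genes in 9 of 27 with 1 rising (adjusted p = 0.0074), Bdh1 by 2.41-fold. With an estimated correlation they had adjusted p = 0.26, adjusted p = 0.41 and adjusted p = 0.41. Hepatocyte transcription factors fell in 5 of 19 and rose in 1 (adjusted p = 0.027, adjusted p = 0.26 with an estimated correlation), a call lost against unoperated rats (adjusted p = 0.063). Lipogenesis, with 4 of 20 lower than sham (adjusted p = 0.13), was called against unoperated rats, with 8 lower (adjusted p = 0.00038).

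Other single genes included Abcb1b, a P-glycoprotein drug exporter, up 8.71-fold, Stac3 down 6.52-fold (-2.7, SE 0.31) and Csad, of taurine synthesis, down 2.84-fold. Acute phase genes rose beyond their level in sham in 5 of 24 (list adjusted p = 0.076), with Lcn2 4.83-fold and Timp1 2.95-fold higher, and in 16 of 24 against unoperated rats (list adjusted p = 4.3e-18). The unfolded protein response rose in 5 of 23 and fell in 1 (adjusted p = 0.092), with Creld2, a chaperone, 1.93-fold higher. Against unoperated rats this list was called (list adjusted p = 1e-04), with 11 of 23 higher and 1 lower. Among markers of other cells, neutrophil genes rose in 5 of 16, with S100a8, a calcium-binding protein, up by 0.59 (list adjusted p = 0.015, adjusted p = 0.29 with an estimated correlation). PH70 rat 139 had the highest neutrophil mean, 0.44 against 0.03 to 0.24 in the other 5 rats, and without it S100a8 was up by 0.35. The list lost its call without rats 95 and 139 (adjusted p = 0.093). There, and also in a fit of the 2 groups alone, 2 of the 16 rose, and S100a8 lost its call in the latter (adjusted p = 0.079). T and NK cell markers fell in 3 of 21 (5 without rats 95 and 139), Cd4 by 0.96 (list adjusted p = 0.015, adjusted p = 0.26 with an estimated correlation), and the list was not called against unoperated rats (adjusted p = 0.38). Endothelial markers fell in 5 of 15 and rose in 1 (adjusted p = 0.051). Krt18 rose by 1.42 and Krt8 by 0.93 on the bile duct and progenitor list, on which they were the 2 of 18 members that rose (list median -0.02, adjusted p = 0.34). In all 3386 genes were called, 1906 higher and 1480 lower, and no alternative other than a 2-fold threshold moved the count by more than 1.5 times.

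**Figure D3:**
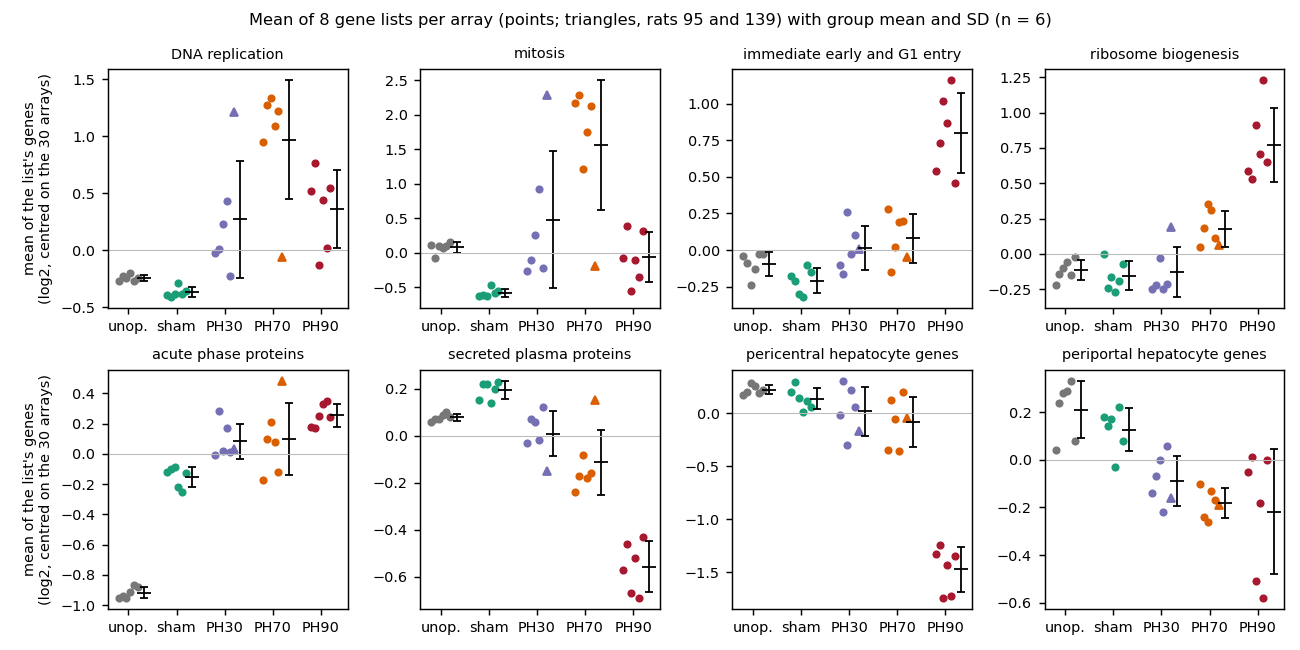
Mean of the genes of 8 lists on each array (log2, relative to the median of the 30 arrays), 1 point per rat, with the mean and SD of each group (n = 6) beside the points; triangles mark PH30 rat 95 and PH70 rat 139. The mitosis mean is 1.56 ± 0.94 in PH70 and -0.06 ± 0.36 in PH90, while the ribosome biogenesis mean is 0.18 ± 0.13 in PH70 and 0.77 ± 0.26 in PH90.

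Removal of 90% of the liver changed more genes and by larger amounts. The neuropeptide gene Npy rose 26.1-fold (4.71, SE 0.16, adjusted p = 1.7e-19), Abcb1b 25.6-fold, the transporter gene Slc16a6 17.2-fold, and Rbm3, an RNA-binding protein induced by cold, 9.13-fold. Sult1c3, a sulfotransferase, fell 51-fold (-5.67, SE 0.15, adjusted p = 1.7e-21), Rgn, a calcium-binding protein also known as SMP30, 45-fold (-5.49, SE 0.16), Car3, a carbonic anhydrase, 39.2-fold, and Kmo, of tryptophan breakdown, 18.6-fold. All these changes were seen in 6 of 6 rats.

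Genes of entry into the cell cycle and of ribosome production rose together. On the immediate early and G1 list 18 of 20 rose and 1 fell (median 1.02, adjusted p = 4.5e-07, adjusted p = 0.037 with an estimated correlation), with Ccnd1 up 4.16-fold (2.06, SE 0.29, adjusted p = 9.6e-07), Ccn1 4.11-fold and Ccn2 3.47-fold (both matricellular proteins), and Myc, a transcription factor of cell growth, 2.52-fold (1.33, SE 0.23, adjusted p = 2.7e-05). Of 27 ribosome biogenesis genes 26 rose and 0 fell (median 0.88, adjusted p = 3.7e-16, adjusted p = 0.067 with an estimated correlation), among them Nop58, 3.06-fold, and Mybbp1a, 2.85-fold. Among 17 p53 targets 12 rose and 1 fell (adjusted p = 0.00065, adjusted p = 0.13 with an estimated correlation), with Tnfrsf10b, a death receptor, 3.54-fold and Cdkn1a 3.19-fold higher.

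More replication than mitosis genes were called, and a difference between the lists was not tested. DNA replication genes rose in 27 of 37 (32 adjusted over the list alone, median 0.67, adjusted p = 1.8e-06, adjusted p = 0.44 with an estimated correlation), among them Mcm6, 2.74-fold, and Ccne1, the cyclin of S phase entry, 2.42-fold (1.27, SE 0.24). Of 37 mitosis genes 1 rose, the phosphatase gene Cdc25c by 0.92 (SE 0.21, adjusted p = 0.00056), and 0 fell (median 0.47, adjusted p = 0.04, adjusted p = 0.71 with an estimated correlation). In a fit of the 2 groups alone 26 of the 37 rose, and the mitosis mean was 0.52 above sham (two-sided exact permutation p = 0.0043). Mki67 differed from sham by 1.02 (SE 0.52, adjusted p = 0.14) and Cdk1 by 0.62 (SE 0.4, adjusted p = 0.26). Both passed without rats 95 and 139 (adjusted p = 0.022 and 0.028), and Cdk1 in a fit of the 2 groups alone (adjusted p = 0.012). Against unoperated rats Mki67 differed by -0.55 (adjusted p = 0.49) and Cdk1 by 0.01 (adjusted p = 0.99). Rrm2, of the replication list, was 2.84-fold higher (1.51, SE 0.6, adjusted p = 0.049) in 5 of 6 rats, a call lost in 10 of the 12 fits that left out 1 array (all but those without PH90 rat 61 or 106, with values from 1.29 to 1.82), and it differed by -0.04 from unoperated rats (adjusted p = 0.98). The mitosis call rests on the choice of control: against unoperated rats the list mean differed by -0.14 (two-sided exact permutation p = 0.39) with a list adjusted p of 0.46. Without rats 95 and 139, 18 of the 37 were called higher than sham. Those rats are in neither group, so leaving them out kept the list median at 0.47 and changed only the shared spread. The SE of Mki67 was then 0.35 in place of 0.52.

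Hepatocyte products and enzymes fell broadly. Secreted plasma proteins fell in 29 of 34 and rose in 1 (median -0.64, adjusted p = 1.8e-17, adjusted p = 0.029 with an estimated correlation), among them Mbl2, a mannose-binding lectin, 6.16-fold, Pros1 4.09-fold and C5 2.97-fold. Alb, albumin, was not among them, with a difference of -0.07 (SE 0.03, adjusted p = 0.11). Its values ran only from -0.11 to 0.11 over all arrays. Whether its signal is compressed on the arrays cannot be examined without levels. P450 genes fell in 21 of 29 and rose in 4 (median -0.82, adjusted p = 3e-09, adjusted p = 0.03 with an estimated correlation), Cyp2c11 by 10.8-fold (-3.44, SE 0.18) and Cyp2e1, the ethanol-metabolising P450, by 5.73-fold. Bile acid genes fell in 16 of 24 and rose in 3 (median -0.96, adjusted p = 1.4e-06, adjusted p = 0.091 with an estimated correlation), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 10.6-fold lower (-3.4, SE 0.49, adjusted p = 1.3e-06), Slc10a1 9.95-fold and Slco1b2, an organic anion importer, 12.5-fold lower. Conjugation enzymes fell in 13 of 23 and rose in 4 (median -1.32, adjusted p = 4.1e-06, adjusted p = 0.067 with an estimated correlation).

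Lipid and hormone genes followed. Lipogenesis genes fell in 14 of 20 and rose in 4 (median -0.89, adjusted p = 1.8e-05, adjusted p = 0.067 with an estimated correlation), with the desaturases Fads1 and Fads2 11.4-fold and 10.8-fold lower. Cholesterol synthesis fell in 14 of 19 and rose in 0 (17 fell adjusted over the list alone, adjusted p = 3.2e-08, adjusted p = 0.16 with an estimated correlation), for example Ebp, a sterol isomerase, 5.06-fold. On the growth hormone list 9 of 19 fell and 5 rose (adjusted p = 0.047, adjusted p = 0.36 with an estimated correlation): Igfals, the carrier of IGF complexes, fell 9.79-fold, Socs2, a target of growth hormone, 7.6-fold, Ghr, its receptor, 5.17-fold and Igf1 1.29-fold. The list was not called in a fit of the 2 groups alone (adjusted p = 0.074). Fatty acid oxidation went both ways, 7 of 27 up and 11 down (adjusted p = 0.05, and 0.01 against unoperated rats), with Plin2, the coat protein of lipid droplets, 3.67-fold higher.

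Zonation genes of the lobule fell unequally. Pericentral genes, expressed in hepatocytes near the central vein, fell in 10 of 15 and rose in 1 (median -1.16, adjusted p = 6.5e-08, adjusted p = 0.037 with an estimated correlation). Periportal genes, of hepatocytes near the portal vein, fell in 7 and rose in 4 of 17 (median -0.24, adjusted p = 0.15, but 0.0035 with fry and 0.039 against unoperated rats), with Uroc1 3.65-fold and Sds, a serine dehydratase, 2.79-fold lower. The pericentral minus the periportal mean per array was -1.25 ± 0.07 (SD, n = 6) in PH90 and 0.01 ± 0.09 in sham (two-sided exact permutation p = 0.0022, the smallest possible). Urea cycle and amino acid genes fell in 18 of 32 and rose in 7 (adjusted p = 0.00026, adjusted p = 0.27 with an estimated correlation), gluconeogenesis and glycogen genes fell in 11 of 16 and rose in 1 (adjusted p = 3e-05, adjusted p = 0.17 with an estimated correlation). Hepatocyte transcription factors fell in 11 of 19 and rose in 3 (adjusted p = 0.001, adjusted p = 0.067 with an estimated correlation), with the bile acid receptor gene Nr1h4 3.47-fold, Ppara 2.66-fold and Cebpa 2.63-fold lower.

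Markers of other cell types went different ways beside these falls. T and NK cell markers fell in 9 of 21 (median -0.18, adjusted p = 0.0013, adjusted p = 0.099 with an estimated correlation) and macrophage markers in 10 of 20, with 2 rising (median -0.24, adjusted p = 0.04, adjusted p = 0.55 with an estimated correlation), Csf1r by 1.07. Against unoperated rats the macrophage list was not called (median -0.07, adjusted p = 0.61), with 6 markers higher and 4 lower. The sinusoidal endothelial genes Oit3 and Clec4g fell by 1.64 and 1.45, on a list of which 5 of 15 fell and 2 rose (median -0.07, adjusted p = 0.1, and 0.0048 with fry). Krt8 and Krt18 rose 7.97-fold and 6.5-fold on the bile duct and progenitor list, on which 4 of 18 rose and 1 fell. Camera did not call that list (median 0.05, adjusted p = 0.18), while fry did (adjusted p = 3.1e-06), and its mean was 0.33 ± 0.09 (SD, n = 6) in PH90 and -0.06 ± 0.05 in sham, with 0.26 the lowest PH90 and 0 the highest sham value. Neutrophil markers rose in 4 of 16 (adjusted p = 0.34, and 0.048 with fry), and against unoperated rats in 7 of 16 (list adjusted p = 0.041). In stellate cell genes Tagln, a smooth muscle protein, rose 5.39-fold and Lrat, of retinoid storage, fell 3.68-fold (6 of 19 up, 6 down, adjusted p = 0.66). In all 6290 genes were called, 3619 higher and 2671 lower. Of these 1013 passed a 2-fold threshold, with fewer higher (444) than lower (569). Each fit with 1 array left out called 5949 to 6225 genes.

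The direct test of PH70 against PH30 gave the least settled result. Of the called genes 6 passed a 2-fold threshold, 5 higher and 1 lower in PH70. Rfc4, a clamp loader subunit, was 2.53-fold higher in PH70 (1.34, SE 0.33, adjusted p = 0.036), Tyms, thymidylate synthase, 2.22-fold (1.15, SE 0.28, adjusted p = 0.035) and Uhrf1, a factor of DNA methylation maintenance, 2.18-fold, each in 5 of 6 rats. Mad2l1, of the spindle checkpoint, was 2.41-fold higher in 5 of 6 rats and Prim1, a primase subunit, 2.3-fold in 6 of 6. Stac3 was 2.42-fold lower (-1.28, SE 0.31, adjusted p = 0.035) in 6 of 6. H2ac20, a histone gene, was 1.91-fold higher (0.93, SE 0.18, adjusted p = 0.018) in 6 of 6 rats, a call kept in all 12 fits that left out 1 array. Of 37 DNA replication genes 9 were called higher (32 adjusted over the list alone) and of 37 mitosis genes 2 (37 adjusted over the list alone), with list medians of 0.62 and 1.08 and list adjusted p of 8.8e-24 and 1.5e-24, both with adjusted p = 0.27 with an estimated correlation. Ribosome biogenesis genes were higher in 3 of 27 (15 adjusted over the list alone), with Ncl up by 0.53 (list adjusted p = 7e-13, adjusted p = 0.27 with an estimated correlation). Endothelial markers were lower in 2 of 15, Clec4g by 1.43-fold and Gpr182 by 1.41-fold (list adjusted p = 0.00038, adjusted p = 0.27 with an estimated correlation). The unfolded protein response was higher in 2 of 23 (adjusted p = 0.0027) and secreted plasma proteins lower in 1 of 34 (adjusted p = 0.00084), with adjusted p = 0.59 and adjusted p = 0.44 with an estimated correlation, and the former was not called without rats 95 and 139 (adjusted p = 0.22). Cholesterol synthesis (median -0.23, adjusted p = 0.0013) and macrophage markers (median -0.2, adjusted p = 0.011) were lower as lists with 0 members called by limma (5 of 19 and 5 of 20 lower at an unadjusted p below 0.05), each with adjusted p = 0.59 with an estimated correlation. P53 targets and oxidative stress genes were higher as lists (adjusted p = 0.024 for both), and growth factors and receptors (adjusted p = 0.019) and T and NK cell markers (adjusted p = 0.036) lower. Limma called 0 members of these 4 lists, and at an unadjusted p below 0.05 it had 4 of 17 higher and 1 lower, 3 of 20 higher, 8 of 30 lower and 6 of 21 lower. With an estimated correlation these had adjusted p = 0.44, adjusted p = 0.36, adjusted p = 0.27 and adjusted p = 0.44.

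The count of 413 genes, 320 higher and 93 lower in PH70, depends on single rats. It was 2420 without rats 95 and 139 and 2178 with array weights, 630 among the upper genes by SD, and 2 both in a fit of these 2 groups alone and with the animal number as a covariate. With 1 array left out it was 1911 without PH30 rat 95 and 1406 without PH70 rat 139. Leaving out another PH30 rat gave 71 (rat 65), 18 (rat 98), 119 (rat 99), 126 (rat 130) or 45 (rat 140), and leaving out another PH70 rat gave 71 (rat 37), 72 (rat 58), 80 (rat 59), 64 (rat 97) or 86 (rat 136). Without rats 95 and 139, 34 of 37 DNA replication and all 37 mitosis genes were called higher, with 12 of 27 ribosome biogenesis, 4 of 23 unfolded protein response, 5 of 17 p53 and 7 of 20 oxidative stress genes, and with 1 p53 and 1 unfolded protein response gene lower. Lower in that fit were 13 of 34 secreted plasma proteins, 8 of 20 macrophage, 5 of 15 endothelial and 5 of 21 T and NK cell markers, 4 of 19 cholesterol genes and 6 of 30 growth factors and receptors. The fit of the 2 groups alone called 0 members of these lists. Rfc4, Mad2l1, Prim1, Uhrf1, Stac3, Clec4g and Gpr182 lost their call in each of the 10 fits that left out 1 rat other than 95 or 139, Tyms in those 10 except without PH30 rat 130, and Ncl without PH30 rat 98. Their changes in the 12 fits ranged from 1.13 to 1.72 for Rfc4, 1.07 to 1.64 for Mad2l1, 0.97 to 1.55 for Prim1, -1.69 to -1.03 for Stac3, 0.98 to 1.45 for Uhrf1, -0.64 to -0.45 for Clec4g, -0.56 to -0.41 for Gpr182, 0.96 to 1.45 for Tyms and 0.48 to 0.62 for Ncl. H2ac20 lost its call with the animal number as a covariate (0.91, adjusted p = 0.058) and in a fit of the 2 groups alone (adjusted p = 0.2), as did the other genes named here.

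PH90 and PH70 livers differed in the cell cycle genes they expressed and in hepatocyte functions. Mitosis genes were lower in PH90 in 36 of 37 (median -1.6, adjusted p = 7.1e-19, adjusted p = 0.26 with an estimated correlation), Mki67 by 6.29-fold (-2.65, SE 0.52, adjusted p = 0.00024), Top2a by 6.2-fold and Ccnb1, the cyclin of mitosis, by 4.58-fold (-2.2, SE 0.45, adjusted p = 0.00043), each below the PH70 mean in 6 of 6 rats. The groups overlapped through PH70 rat 139, whose Mki67 value (-0.26) lay below those of PH90 rats 39 (-0.25), 111 (0.36) and 43 (0.78). DNA replication genes were lower in 18 of 37 (25 adjusted over the list alone, 31 without rats 95 and 139, 10 in a fit of the 2 groups alone; median -0.56, adjusted p = 1.9e-08, adjusted p = 0.4 with an estimated correlation), Rrm2 by 8.97-fold. At the same time immediate early and G1 genes were higher in 13 of 20 (median 0.66, adjusted p = 1.2e-06, adjusted p = 0.05 with an estimated correlation), with Ccn1 and Ccn2 each 3.21-fold and Klf6 2.83-fold higher, and ribosome biogenesis genes in 26 of 27 (median 0.63, adjusted p = 7.8e-14, adjusted p = 0.1 with an estimated correlation), with Mybbp1a 2.13-fold higher. Myc was 1.91-fold higher (0.94, SE 0.23, adjusted p = 0.0029), while Ccnd1 differed by 0.56 (SE 0.29, adjusted p = 0.18).

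Pericentral genes were lower in 9 of 15 (median -1.23, adjusted p = 4.3e-12, adjusted p = 0.013 with an estimated correlation), Rgn by 30.3-fold and Cyp2e1 by 4-fold. Periportal genes went both ways, 5 of 17 higher and 3 lower (median -0.05, adjusted p = 0.97): Arg1, arginase of the urea cycle, was 2.32-fold higher (1.22, SE 0.1) and Hsd17b13, a lipid droplet enzyme, 3.53-fold lower. P450 genes were lower in 17 and higher in 4 of 29 (adjusted p = 1.1e-08, adjusted p = 0.04 with an estimated correlation), Cyp3a2 by 5.25-fold. Secreted plasma proteins were lower in 24 and higher in 2 of 34 (adjusted p = 4.1e-13, adjusted p = 0.04 with an estimated correlation), Mbl1 by 3.85-fold. Lipogenesis genes were lower in 10 and higher in 3 of 20 (adjusted p = 2.1e-06, adjusted p = 0.05 with an estimated correlation) and bile acid genes lower in 14 and higher in 2 of 24 (adjusted p = 5.6e-07, adjusted p = 0.097 with an estimated correlation), Cyp7a1 by 10.1-fold. The unfolded protein response went both ways, 4 of 23 higher, Edem1 by 3.23-fold, and 10 lower, Sdf2l1 by 2.2-fold (adjusted p = 0.038, adjusted p = 0.61 with an estimated correlation). Of 20 hypoxia genes 7 were higher and 1 lower (adjusted p = 0.04, adjusted p = 0.34 with an estimated correlation), Aldoa, an enzyme of glycolysis, by 2.62-fold and Slc2a1, a glucose transporter, by 1.78-fold. Urea cycle and amino acid genes were higher in 9 and lower in 14 of 32 (adjusted p = 0.038, adjusted p = 0.55 with an estimated correlation), with Got1, an aminotransferase, 5.34-fold higher and Uroc1 3.05-fold lower. P53 targets were higher in 7 and lower in 2 of 17 (adjusted p = 0.035, adjusted p = 0.37 with an estimated correlation), and Tnfrsf10b was 2.21-fold higher. The calls of these 4 lists were lost without rats 95 and 139, with adjusted p of 0.13 for the unfolded protein response, 0.085 for hypoxia, 0.082 for urea cycle and amino acid genes and 0.072 for p53 targets. Their medians were -0.13, 0.1, -0.39 and 0.28 in place of -0.28, 0.11, -0.33 and 0.34, and 3 hypoxia genes were lower in place of 1. In a fit of the 2 groups alone they were lost as well (adjusted p = 0.067, 0.061, 0.13 and 0.054).

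Some genes were far above PH70 in PH90. Npy was 25-fold higher (4.64, SE 0.16), Gstm3, a glutathione transferase, 11.9-fold, Faxdc2 11.2-fold, Cdh17, an intestinal cadherin, 8.9-fold and Rdh16 6.26-fold. Krt8 was 4.19-fold higher, one of 4 of 18 bile duct and progenitor genes that were higher, with 0 lower (list median 0.06, adjusted p = 0.19, and 0.00057 with fry). In all 4454 genes were called, 2558 higher and 1896 lower in PH90, and fits without 1 array gave 3966 to 4525. The balance turned at a 2-fold threshold, with 169 higher and 409 lower. Against PH30, 5715 genes were called, 3343 higher and 2372 lower, and at a 2-fold threshold 302 were higher and 406 lower. Npy was 28.3-fold and Cdh17 15.9-fold higher than in PH30, and Rgn 36-fold, Sult1c3 32.4-fold and Fads2 12.7-fold lower. Ribosome biogenesis was higher in 26 of 27 (median 0.9, adjusted p = 9.3e-19) and immediate early and G1 genes in 14 of 20 (adjusted p = 8.6e-06), each with adjusted p = 0.055 with an estimated correlation. Mitosis genes had a median of -0.53 against PH30 with 1 of 37 higher and 0 lower (adjusted p = 0.0085, adjusted p = 0.8 with an estimated correlation), and DNA replication genes one of 0.1 with 0 of 37 called (adjusted p = 0.66), although 13 of them were called higher without rats 95 and 139 (list adjusted p = 0.0093). Without those rats the mitosis median was -0.19 (list adjusted p = 0.2). Pericentral genes were lower than in PH30 in 10 of 15 (median -1.62, adjusted p = 6.8e-09, adjusted p = 0.051 with an estimated correlation).

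Over the 3 resections together, limma's F test called 5882 genes. The means of 42.2% of them rose from PH30 to PH70 and again to PH90, those of 27.6% fell at both steps, 15.2% fell and then rose, and 15% rose and then fell. These profiles use only the sign of each difference in means, whatever its size. In the direct tests limma called 413 genes from PH30 to PH70 and 4454 from PH70 to PH90. For most of the 5882 genes the first step was therefore not called, and the profiles do not show a graded response.

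Genes called against sham were partly shared between the sizes. PH30 and PH70 shared 814 genes called in the same direction, 320 higher and 494 lower, where independent lists would share 41.9 and 49.4, and 0 genes had opposite directions. PH30 and PH90 shared 677 with 31 opposite (independent lists 79.5 and 89.1), and PH70 and PH90 2480 with 44 opposite (379.7 and 217.6). In all 3 comparisons 241 genes were higher and 385 lower. The comparisons use the same sham arrays. Simulated unchanged groups with a common control, made from residuals of arrays of all groups, shared 0 genes. They hold no effects and so do not measure how much of the overlap comes from the shared arrays. With separate parts of the sham group for each comparison, which leaves 3 control arrays each, the medians over 20 divisions were 82.5, 77.5 and 1475 shared genes, where independent lists of those sizes would share 6.6, 15.3 and 332.7. Without rats 95 and 139 the first 2 pairs shared 1345 and 1077. The fold changes of PH30 and PH70 correlated at 0.83 across genes, which are not independent replicates, those of PH30 and PH90 at 0.49 and those of PH70 and PH90 at 0.63, against 0.53 in simulated unchanged groups, and at 0.72, 0.43 and 0.59 with separate parts of the sham group. Their covariances were 0.0529, 0.0496 and 0.0988, against 0.0069 in the simulation.

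**Figure D4:**
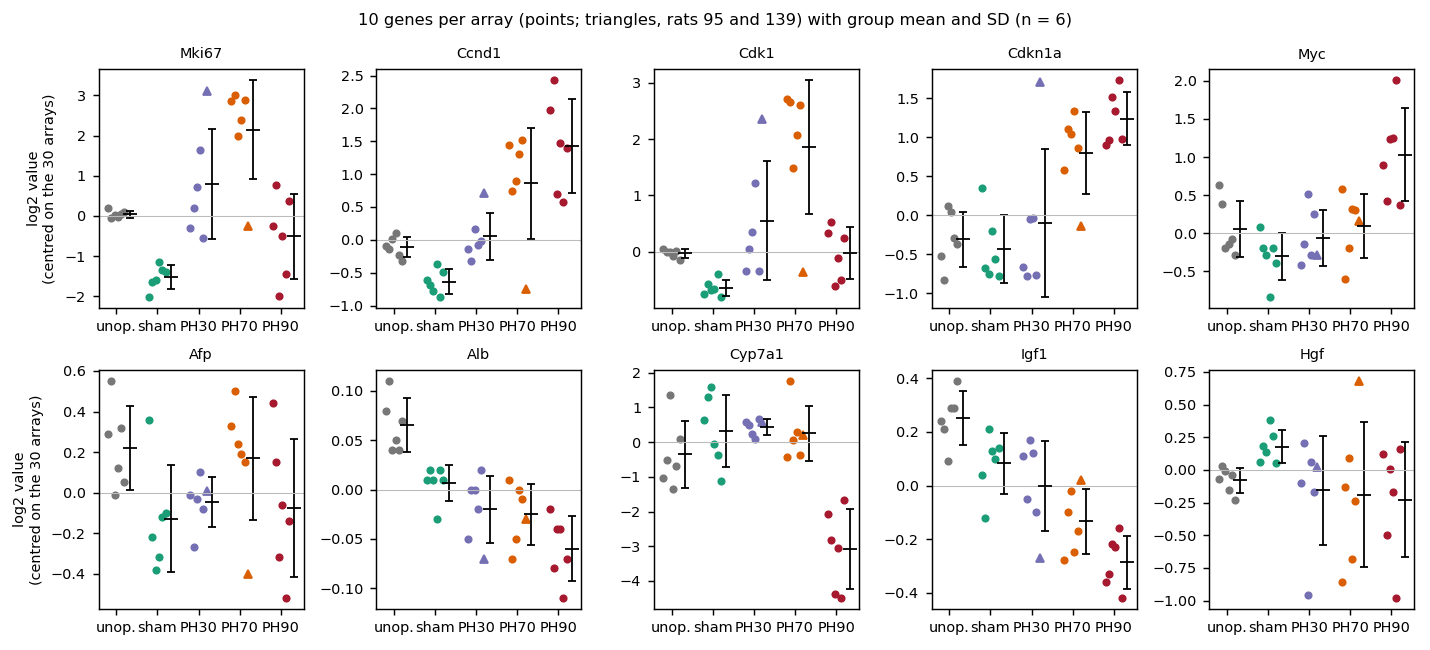
Values of the 10 genes followed in every comparison on each array (log2, relative to the median of the 30 arrays), 1 point per rat, with the mean and SD of each group (n = 6); triangles mark PH30 rat 95 and PH70 rat 139. Mki67 peaks in PH70 at 2.15 ± 1.24, while Cyp7a1 is low in PH90 alone of the 5 groups, at -3.08 ± 1.16.

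The 10 genes followed in every comparison gave different profiles. Mki67 was called in PH30 and PH70 against sham and lower in PH90 than in PH70, and Cdk1, the kinase of mitosis, in PH70 against sham (2.5, SE 0.4, adjusted p = 4.8e-05) and PH90 against PH70 (-1.88, SE 0.4, adjusted p = 0.00063) but not in PH30 (1.19, adjusted p = 0.076; 0.83 and adjusted p = 0.021 without rats 95 and 139). Ccnd1 and Cdkn1a were called higher in PH70 and PH90 but not in PH30 (0.69, adjusted p = 0.17, and 0.34, adjusted p = 0.6). In a fit of PH30 and sham alone Ccnd1 was called (adjusted p = 0.013), and without rats 95 and 139 Cdkn1a differed by -0.02. Myc was called in PH90 but not in PH70 (0.4, adjusted p = 0.28) or PH30 (0.24, adjusted p = 0.63). Cyp7a1 was called against sham in PH90 only, with differences of 0.11 in PH30 and -0.07 in PH70, and it fell by 3.33 on the log2 scale from PH70 to PH90. Igf1 was 1.29-fold lower in PH90 than in sham (-0.37, SE 0.07, adjusted p = 0.00012) and differed by -0.22 in PH70 (adjusted p = 0.033), a call lost without PH70 rat 37, 97 or 136 or sham rat 45, 112, 114 or 143, where it ranged from -0.26 to -0.19 over 12 such fits, and with the animal number as a covariate (-0.21, adjusted p = 0.064). It was also lower in PH90 than in PH30 (-0.28, SE 0.07, adjusted p = 0.0026) but not called against PH70 (-0.15, adjusted p = 0.14). Afp, alpha-fetoprotein of the fetal liver, Alb and Hgf, the hepatocyte growth factor, were called in 0 of the 7 comparisons. Without rats 95 and 139 Afp (0.41, adjusted p = 0.025) and Hgf (-0.54, adjusted p = 0.035) were called in PH70, and against unoperated rats Alb was in PH70 (-0.09, adjusted p = 0.046) and PH90 (-0.13, adjusted p = 0.002). The differences of Afp from sham were 0.08, 0.3 and 0.05 in PH30, PH70 and PH90, those of Alb -0.03, -0.03 and -0.07, and those of Hgf -0.34, -0.37 and -0.41. In sham against unoperated rats 0 of these 10 genes was called by limma, and Mki67 had the smallest adjusted p (0.18). In a fit of these 2 groups alone 4 of the 10 were called, Mki67 (adjusted p = 7.2e-07), Cdk1 (-0.61, adjusted p = 5.2e-05) and Ccnd1 (-0.52, adjusted p = 0.0031) lower and Hgf higher (0.26, adjusted p = 0.04), and without rats 95 and 139 Mki67 was (adjusted p = 0.015).

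The direct tests between sizes give the differences that such lists of calls leave open. From PH30 to PH70 0 of the 10 genes was called by limma, with differences of 1.34 for Mki67 (adjusted p = 0.16), 1.31 for Cdk1 (adjusted p = 0.073), 0.89 for Cdkn1a (adjusted p = 0.11), 0.81 for Ccnd1 (adjusted p = 0.12) and 0.16 for Myc (adjusted p = 0.79). Mki67, Cdk1, Cdkn1a and Ccnd1 were called when PH30 rat 95 or PH70 rat 139 was left out, with values of up to 1.83, 1.76, 1.25 and 1.13. From PH30 to PH90 Ccnd1 (2.59-fold), Cdkn1a (2.52-fold) and Myc (2.13-fold) were higher and Cyp7a1 11.5-fold lower in 6 of 6 rats. Mki67 differed by -1.31 (adjusted p = 0.055), a value that passed without PH30 rat 65 or 140 or PH90 rat 43 or 111. With 1 array left out it ranged from -1.58 to -0.85, and without rats 95 and 139 it was -0.85 (adjusted p = 0.074). Cdk1 differed by -0.57 (adjusted p = 0.32). Cdkn1a did not pass from PH70 to PH90 (0.44, adjusted p = 0.36).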

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

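The tests of the labels of rats 95 and 139 were chosen after the values were seen, while the other ways of grouping the rats were planned. Arrays standing apart were sought in 240 sets of 6 values, 1 set per group for 34 list means, 10 genes and 4 array measures, by the gap between the farthest value and its neighbour as a share of the range, with Dixon's 95% critical value as the limit. Chance passes about 1 in 20 sets. The limit was passed in 21 sets, 13 of them by PH30 rat 95 or PH70 rat 139. For rat 139 these were the mean correlation with its group (gap 0.92 of the range), the first and second components (0.768 and 0.72), DNA replication genes (0.723), p53 targets (0.682), macrophage markers (0.667), Mki67 (0.694) and Ccnd1 (0.656). Rat 95 passed it for the mean correlation with its group (0.818), growth factors and receptors (0.816), p53 targets (0.791), the growth hormone list (0.741) and Cdkn1a (0.703). Among the genes named in the text, an array stood apart in PH70 for 26 of 122 genes, 23 times rat 139, and in PH30 for 14, 10 times rat 95, against 8 in PH90, 7 in sham and 12 in unoperated rats.

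PH30 rat 95 lay nearer to the PH70 mean (root mean square distance 0.225 on the log2 scale) than to the PH30 mean (0.355), and PH70 rat 139 nearer to sham (0.225) and PH30 (0.259) than to PH70 (0.345). These were the 2 of 30 arrays whose nearest group mean was not their own. An exchange of these 2 labels would place rat 139 among the PH30 arrays, but its distance to PH30 minus that to sham was 0.034, against -0.059 ± 0.015 (SD, n = 5) in the other PH30 arrays, and its distance to PH30 was above their 0.174 to 0.218. A sham array under the wrong label would lie within the 0.162 to 0.191 of the sham arrays, and rat 139 at 0.225 did not. Other exchanges, a smaller or larger resection than planned, and a slower or faster response of single animals were not tested and stay open.

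The remaining single arrays were sham rat 41 for lipogenesis genes (gap 0.696 of the range), PH90 rat 43 and unoperated rat 147 for T and NK cell markers (0.706 each), sham rat 141 for endothelial markers (0.656), sham rat 112 for Alb (0.706), PH70 rat 58 for Cyp7a1 (0.67), PH30 rat 99 for Hgf (0.673) and unoperated rat 145 for the SD over probe sets (0.636). Of the 10403 probe sets listed with no gene, which enter none of the comparisons above, 1403 were called in PH90 against sham (703 higher, 700 lower), against 38 in sham against unoperated rats.

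Other splits of the same 12 rats, 100 per comparison with the real one included, tested whether chance assignment gives as many called genes. For sham against unoperated rats 1 of 100 splits, the real one, gave 134 genes, and the highest other gave 1. For PH30, PH70 and PH90 against sham the real split was again the 1 that gave as many (1005, 3386 and 6290 genes, highest others 8, 2650 and 3788), as it was for PH90 against PH70 (4454, highest other 2574), PH90 against PH30 (5715, highest other 4695) and the F test over 18 rats (5882, highest other 3091). Chance is therefore unlikely for these 7 counts, and 1 in 100 is the smallest share that this number of splits can show. For PH70 against PH30, 6 of 100 splits gave 413 genes or more, up to 1211, so chance cannot be excluded, and a split with several times the real count points to a structure of the samples other than their groups. The number of lists called by camera with a preset correlation was reached by 6 of 100 splits in sham against unoperated (11 lists, highest other 16), 24 in PH30 (11, 15), 5 in PH70 (18, 22) and 9 in PH90 against sham (18, 21), 22 in PH70 against PH30 (12, 18), 8 in PH90 against PH70 (18, 20) and 11 in PH90 against PH30 (17, 20). Chance cannot be excluded for any of these 7 numbers of lists. A split of rats from groups that differ can hold part of the real difference, and the number of lists tests no single list. In the same order, the other splits called a median of 3, 7, 9, 11, 8, 10 and 11 lists. Camera with a preset correlation thus called many lists where rats were regrouped at random, and its adjusted p values are descriptive.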

How the results depend on the processing

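Fits without rats 95 and 139, with the probe set of largest SD and with the upper genes by SD were chosen after the data were seen. For PH70, PH90, PH90 against PH70 and against PH30, and the F test, counts stayed within 1.5 times under every alternative except the 2-fold threshold, which left 17, 38, 291 and 1013 genes in sham against unoperated, PH30, PH70 and PH90 against sham, and 6, 578 and 708 in PH70 against PH30 and PH90 against PH70 and PH30. Array weights gave 539 genes for sham against unoperated, 1938 for PH30 and 2178 for PH70 against PH30. A fit of only the groups compared gave 721 (228 higher and 493 lower, 31.6% higher in place of 41.8%) and 2 for the first and last of these, and 2 for the last with animal number as a covariate, which also left out the unoperated rats. Without rats 95 and 139 the 3 counts were 316, 1984 and 2420. The upper genes by SD gave 630 for PH70 against PH30, with fewer genes tested, and unoperated control 1789 for PH30. With 1 array left out the ranges were 70 to 139 for sham against unoperated (without unoperated rats 152 and 147), 626 to 1527 for PH30 (without its rats 65 and 95) and 18 to 1911 for PH70 against PH30 (without PH30 rats 98 and 95). With an estimated correlation 1, 0, 0, 4, 0, 3 and 0 of the 34 lists were called for sham against unoperated, PH30, PH70 and PH90 against sham, PH70 against PH30, and PH90 against PH70 and PH30, in place of 11, 11, 18, 18, 12, 18 and 17. Fry called 1, 5, 28 and 6 lists in sham against unoperated, PH30, PH90 and PH70 against PH30, and a fit of only 2 groups 17 in sham against unoperated. Genes shared by PH30 and PH70, PH30 and PH90, and PH70 and PH90 numbered 82.5, 77.5 and 1475 (medians) with separate parts of the sham group, with fewer arrays, 36, 20 and 105 at 2-fold, and 1345 and 1077 for the first 2 without rats 95 and 139. Against unoperated rats 4 results called with 1 of the 2 controls turned: Hbb-b1 in PH30 (0.46), Rrm2 in PH90 (-0.04), the unfolded protein response in PH30 (adjusted p = 0.026) and mitosis in PH90 (adjusted p = 0.46); the cause was not tested. Values called with neither control also changed sign, such as Mki67 in PH90 (-0.55) and Cyp7a1 in PH70 (0.61). Of the 802 gene values open to naming 650 were called, 531 of them in every fit with 1 array left out: 18 of 31 in sham against unoperated, 30 of 61, 103 of 124 and 133 of 139 in PH30, PH70 and PH90 against sham, 1 of 29 in PH70 against PH30, and 126 of 134 and 120 of 132 in PH90 against PH70 and PH30. Of 227 values followed through the alternatives, a robust prior and the probe set of largest SD changed 0 calls, as did median centring, which moved arrays by 0.022 at most and so tests little, all probe sets ended 4, the covariate and a fit of 2 groups 12 each and unoperated control 4, besides the 2 that turned. Signal over background is not known for these centred values. Filtering by level, quantile normalization and a level-dependent prior were not run.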

Other observations

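The tests of explanations in this part and the 4 relations within PH90 were chosen after the values were seen, while the list tests were planned. In PH90 livers single genes of stress, growth signals and rhythm also changed, on lists that camera did not call against sham. Of 20 oxidative stress genes 11 rose and 6 fell (adjusted p = 0.13, and 0.00023 with fry), with Srxn1, sulfiredoxin, 2.42-fold (1.27, SE 0.13) and Hmox1, heme oxygenase, 2.19-fold higher than in sham. Hypoxia genes rose in 7 and fell in 3 of 20 (adjusted p = 0.15, and 3.4e-05 with fry). Against unoperated rats the hypoxia list was called (list adjusted p = 0.039), with 9 higher and 3 lower. The 2 named here belong to glycolysis: Aldoa rose 3.24-fold over sham (1.7, SE 0.09, adjusted p = 4e-15) and Ldha 2.02-fold. Growth factors and their receptors went both ways, 9 of 30 up and 9 down (median 0.01, adjusted p = 0.5, although fry called the list lower at adjusted p = 0.0056), with Egfr, the receptor of epidermal growth factor, 3.43-fold lower (-1.78, SE 0.12, adjusted p = 7.5e-13). Cytokines rose in 6 and fell in 5 of 25 (adjusted p = 0.84), and Il33, an alarmin, fell 3.41-fold. On the acute phase list 12 of 24 rose and 4 fell against sham (adjusted p = 0.19, 0.026 with fry, and 6.5e-08 against unoperated rats), with Lcn2 6.65-fold and Timp1 4.04-fold higher.

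Circadian clock genes fell in 5 and rose in 2 of 15 in PH90 (median 0.02, adjusted p = 0.24, although fry called the list lower at adjusted p = 0.00029): Bmal1 was 2.03-fold and its relative Npas2 2.23-fold lower and Per1 2-fold higher. In PH30 and PH70 0 and 1 of the 15 changed (list adjusted p = 0.61 and 0.35). Among other cell markers in PH90, B and plasma cell genes fell in 3 of 12 (adjusted p = 0.1, and 1e-05 with fry), red cell genes fell in 4 and rose in 1 of 15 (adjusted p = 0.35), and platelet genes fell in 2 of 10 (adjusted p = 0.49). The unfolded protein response went both ways, 6 of 23 up and 7 down (adjusted p = 0.7).

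The low mitosis genes in PH90 against PH70, beside higher G1 and ribosome genes, were weighed against 2 technical explanations. A lower share of hepatocytes would lower the genes of hepatocytes together, but the periportal genes had a median of -0.05 (quartiles -0.21 and 0.56) where the mitosis genes had -1.6 (quartiles -1.88 and -1.46). Other hepatocyte lists were lower, with medians of -1.23 for pericentral and -0.72 for P450 genes. Fatty acid oxidation genes had 0.04. The periportal values argue against a lower share, equal across the lobule, as the whole cause of the low mitosis genes, and a part stays open. A loss of hepatocytes that differs between zones was not tested. A difference in scaling left in these values would move every gene of an array alike. The 146 marker genes of other cells had a median of -0.03 (quartiles -0.17 and 0.08). RMA had equalised the arrays, and the median over all genes was 0.009, so this shows only that no common shift was left. It cannot decide about differences removed by RMA. A candidate biological explanation, as a hypothesis, is that 24 hours after the largest resection more cells had entered G1 and fewer had reached mitosis, and a single time point cannot tell a delay from a block.

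The fall of pericentral beyond periportal genes in PH90 was weighed in the same way. The pericentral minus periportal mean per array differed by -1.35 on the log2 scale between PH90 and PH70 (PH90 -1.25 ± 0.07, PH70 0.1 ± 0.28, SD, n = 6). A lower share of hepatocytes, equal in both zones, would lower both lists alike and leave their difference unchanged. These values therefore argue against such an equal loss, relative to PH70, as the whole cause. A loss of hepatocytes that differs between the zones would change the difference, was not tested and stays open. A lower share would also raise the markers of every other cell type alike. Such a rise would not by itself explain a difference between 2 hepatocyte lists. Against sham the 9 marker lists moved apart, 2 with higher and 4 with lower means per array (exact permutation tests adjusted over the 9 lists), from -0.33 for endothelial cells (adjusted p = 0.0097) to 0.39 for bile duct and progenitor cells (adjusted p = 0.0065). The latter mean rests largely on Krt8 and Krt18, which rose by 3 and 2.7 while the list median was 0.05. Krt18 is shared with hepatocytes, so that list is a weak marker of other cells. The 4 lists with lower means argue against a lower share than in sham as the whole cause. Against PH70 1, the bile duct and progenitor list, was higher and 0 were lower, the lowest at -0.12 (T and NK cells, adjusted p = 0.058). The markers thus leave open whether the share was lower than in PH70. A lower share that is equal in both zones would still leave the difference between the 2 lists unchanged. The 2 pericentral genes with the largest falls, Rgn and Car3, carry part of it and not all: without them the difference was -0.86 (PH90 -0.71 ± 0.07, PH70 0.15 ± 0.26), and against sham it was -0.68 in place of -1.27. A biological cause was not tested. Which part of the remnant was sampled is not given in the sources used here, and compression of strong signals on the arrays cannot be examined without levels, so both stay open.

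Within PH90 the rats differed, and 4 relations of the mitosis mean with other list means were computed over the 6 rats. Rats with higher mitosis means had higher pericentral means (Pearson r = 0.91, exact permutation p = 0.021, adjusted p = 0.044 over the 4 relations; Spearman rho = 0.94, exact permutation p = 0.017, adjusted p = 0.066). Without rats 61 and 106, the 2 farthest from the pericentral median, r was 0.75 over the 4 other rats, too few for a test. With secreted plasma proteins r was 0.94 (adjusted exact permutation p = 0.044), with rho 0.83 (adjusted 0.077), and 0.9 without the same rats. With immediate early and G1 genes r was -0.75 and with ribosome biogenesis -0.73 (adjusted exact permutation p = 0.094 for both). The hypothesis that PH90 livers that keep more mature hepatocyte expression may be those with more mitosis thus passed by r and not by rho, on 6 rats and with an array-wide factor such as RNA quality not excluded. Rats 61 and 106, with the lowest mitosis means (-0.55 and -0.35), also had the highest first-component values (55.33 and 59.45) and SD over probe sets (0.446 and 0.478). A relation with the size of the whole response was not tested, so one particular to mature hepatocyte genes is not shown.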
